A study of Mus musculus with 6 samples.

How the data were processed

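RNA sequencing of mouse neural stem cells was analysed from 6 libraries, 3 with a control hairpin (shControl) and 3 with a hairpin against Mina53, gene symbol Riox2 (shMina53). Per the labels, cells were kept under proliferation conditions and total RNA was taken with Trizol. The authors deposited 1 table of 25996 genes with a signal column for each of the 6 libraries, a signal column for the mean of each group, and a p-value column. The deposited signal is a read count divided by 1 factor per library: every value of a column was a whole multiple of 1 step at a tolerance of 0.01 reads, so the whole reads could be recovered for 100% of the values. The p-value deposited by the authors comes with no statement of its test, but it equalled the p-value of a DESeq2 Wald test on the recovered reads (Spearman correlation 1 over genes, median absolute difference of log10 p 1.1e-06). The submitters' processing notes name CASAVA, HISAT2 2.0.4, UMI-tools, StringTie 1.3.4d, DESeq2 and edgeR, and the build mm10, without their roles. Whether reads were deduplicated by molecular identifiers and whether they were counted by strand is not given. Overlapping genes on opposite strands can therefore share reads: 45 of the 100 named genes overlap another gene, 30 of them one on the other strand, and for 17 that gene's mean was above 0.1 times their own.

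The recovered totals were 13753857 to 16811085 reads per library. At this depth, genes with 3 reads or fewer in a group are given as a ratio with a 95% counting interval (exact, conditional on the sum), and genes with 0 reads as a bound against a floor of 3 reads over the group.

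Before the data were examined, the groups, the main test for each kind of table, the gene lists, the rule for named genes and the first set of other settings were fixed. That plan expected either counts or values such as FPKM; the scaled counts were treated as normalized values. The main test was limma-trend (limma 3.58.1, R 4.3.3; eBayes with trend and robust) on log2 of the scaled count plus 1, for 21500 genes with a mean of at least 1 over the 6 libraries, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Groups were compared without covariates. As a second tool, chosen after the data were seen, edgeR 4.0.16 (quasi-likelihood test, TMM, filterByExpr, robust) was run on the recovered reads for 15082 genes, and DESeq2 1.42.0 for comparison with the deposited p-values. Single measures of a library were compared by an exact two-sided permutation test, which cannot give a p under 0.1 for 3 libraries against 3.

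Gene lists were tested with camera at a preset correlation of 0.01, for lists with at least 5 tested members, adjusted over the 30 lists tested; camera with an estimated correlation and fry were alternatives. Of the tested members, 20 genes are on more than 1 list, such as Hes1, Hes5, Ccnd1 and Gli3. Where a symbol had more than 1 table entry, the one with the highest mean was used, a choice made after the data were seen. The lists were neural stem and progenitor identity, neuronal differentiation, astrocytes, oligodendrocyte lineage, DNA replication, mitosis, p53 targets and cell cycle inhibitors, the Notch pathway, Wnt targets, the Hedgehog pathway, BMP and TGF-beta response, large and small ribosomal subunit proteins, ribosome biogenesis, arginine methyltransferases and related JmjC enzymes, Polycomb complexes, Hox genes, interferon response, integrated stress and unfolded protein response, immediate early genes, cholesterol biosynthesis, glycolysis, oxidative phosphorylation, mitochondrially encoded transcripts, extracellular matrix, apoptosis, and markers of microglia and macrophages, endothelial, fibroblast and mural, ependymal and erythroid cells. Neurod2 and Mx1 had no read in 1 group; with each at its bound the medians of their lists were the same.

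Named genes are Riox2, the 8 called genes with the largest rise and the 8 with the largest fall among those with a symbol, a mean of at least 2 in the higher group and no overlap between groups, and up to 4 members with the smallest adjusted p from each list that passed and from the neural stem cell, neuronal, astrocyte, oligodendrocyte, replication, mitosis, p53, Notch and arginine methyltransferase lists. Other genes named in the text (Crybg3, Lims2, Ptprz1, Mobp, Olig1, Olig2, Cnp, Map2 and those marked so in place) were chosen after their values were seen. Some single list members are not reported here. Positions, transcript lengths and GC content come from GENCODE M21 on mm10 (GRCm38). The length trend was measured over 11377 protein-coding genes with a mean of at least 50 and removed, as an alternative, by a lowess curve per library with a span of 0.3. Alternatives for the pseudocount, filter, scaling, variance model, replicate block, each left-out library, tool and length or GC trends were run one at a time. The pipeline was tested on simulated data of 15082 genes with 3 libraries per group. A shifted list of 30 genes was called and 0 of 29 unshifted lists were called by camera. Genes were simulated independently of each other, so this cannot show how camera behaves on lists of correlated genes. In the real data the estimated correlation was 0.802 for the large ribosomal subunit.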

Results

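RNA was measured by sequencing in mouse neural stem cells, the dividing cells of the embryonic or adult brain that can give rise to neurons, astrocytes and oligodendrocytes, grown under proliferation conditions. A short hairpin RNA against Mina53 (gene symbol Riox2) was used in the cells of 3 libraries, called shMina53 here, and a control hairpin in those of 3 others, called shControl. Riox2 encodes a JmjC-domain oxygenase of the nucleus and nucleolus. The deposited table held 25996 genes, each with a read count scaled by 1 factor per library, here called scaled counts. The recovered totals were 16257593, 16024363 and 16811085 reads in shControl 1, 2 and 3 and 16017753, 14921435 and 13753857 in shMina53 1, 2 and 3. Values are mean ± SD over n = 3 libraries per group, fold changes are log2 of shMina53 over shControl with their standard error, and adjusted p-values are two-sided limma tests over 21500 genes unless another test is named. Coordinates are 1-based on mm10.

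The comparison asked which transcripts of neural stem cells changed when Mina53, named in the series title as an arginine demethylase, was reduced. Riox2 (ENSMUSG00000022724; chromosome 16, 59471775 to 59492461, plus strand) itself fell from 310.1 ± 21.3 scaled counts in shControl to 122 ± 2.14 in shMina53, a log2 fold change of -1.34 (SE 0.146). Its level in the knockdown was 39.4% of the control. The series held no rescue and no further knockdown condition, so other effects of the hairpin cannot be told apart from the loss of Riox2. Genes of glycolysis, cholesterol synthesis, the cytosolic ribosome, the stress response and the oligodendrocyte lineage were lower in shMina53, whereas the astrocyte gap junction gene Gja1, mitochondrially encoded transcripts and the retinoid enzyme gene Aldh1a1 were higher. The lists behind these gene groups passed camera with its preset correlation, but none did with an estimated correlation (adjusted p = 0.321 for each), and the ribosomal and stress lists did not pass fry either (adjusted p = 0.106 and 0.062). In all, 1776 genes were called at an adjusted p under 0.05, of which 815 were higher and 961 lower in shMina53. Of these, 182 at least doubled and 127 at least halved. edgeR on the recovered reads called 1801 genes, 823 higher and 978 lower, of which 1662 were also called by limma, all 1662 in the same direction.

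Riox2 passed the limma test (adjusted p = 9.1e-05), with every shMina53 library (121, 125 and 121 scaled counts) under every shControl library (290.4, 333 and 307). An exact two-sided permutation test gave p = 0.1, the smallest that 3 libraries against 3 allow. Riox2 shares 1687 bases with Crybg3, which lies on the other strand and was higher in shMina53 (186 ± 58.9 against 332 ± 41.4 scaled counts; log2 fold change 0.88), and whether the reads were counted by strand is not given. Of the 1776 called genes, 1766 had no overlap between the groups. Among all tested genes the share without overlap was 29.1%, where chance gives 10%. The number of calls moved with the libraries used. It was 2794 without shControl 1, 661 without shControl 2 and 2503 without shControl 3. It was 1058 without shMina53 1, 595 without shMina53 2 and 497 without shMina53 3. limma without its trend and robust steps called 32 genes. The submitters do not say whether replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

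**Figure D1:**
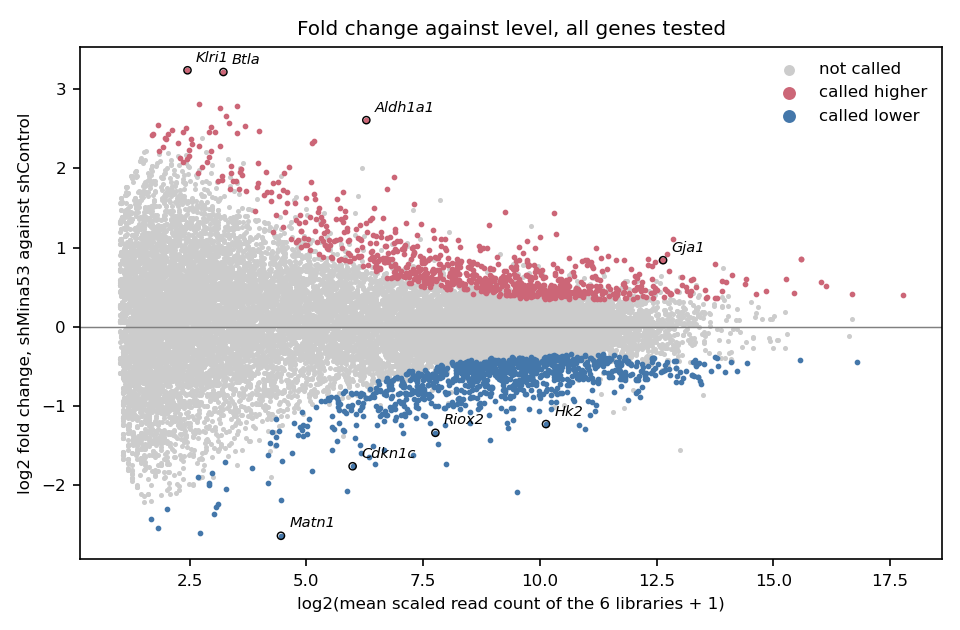
Log2 fold change of shMina53 over shControl (vertical axis) against the mean level over all 6 libraries (horizontal axis, log2 of the mean scaled count plus 1), 1 point per tested gene, with called genes coloured by direction. Riox2 lies at -1.34, Aldh1a1 at 2.61 and Matn1 at -2.63.

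Among the 8 largest rises, that of Aldh1a1 rested on the most reads. This gene (ENSMUSG00000053279; chromosome 19, 20492715 to 20643465, plus strand), which encodes a retinaldehyde dehydrogenase, went from 21.1 ± 4.53 to 133 ± 15.5 scaled counts (log2 fold change 2.61, SE 0.243; adjusted p = 5.6e-05). Matn1 (ENSMUSG00000040533; chromosome 4, 130944385 to 130955475, plus strand), a gene of the matrix protein matrilin 1, had the largest fitted fall, from 35.9 ± 12.3 to 6.01 ± 5.72 (-2.63, SE 0.512; adjusted p = 0.00493), but was not called without shMina53 3 (adjusted p = 0.0538). The other genes at both ends rested on few reads. Klri1, a killer-cell lectin-like receptor gene, had no read in shControl and 26 in shMina53, at least 9.48-fold higher against a floor of 3 reads over the group. Btla, an immune co-receptor gene, had 3 and 45 reads, a ratio of 16.6 (95% counting interval 5.32 to 83.4), and Cc2d2b had 3 and 29 reads, a ratio of 10.7 (3.31 to 54.8). Gm15319 (2.78), Gm20482 (2.76), Gm42892 (2.66) and the hyaluronan link protein gene Hapln1 (2.57) completed the 8 largest rises. On the other side, the zinc transporter gene Slc39a4 (16 reads against 0) was at least 4.82-fold lower and Gm43421 (14 against 0) at least 4.23-fold lower. Gm37613 had a ratio of 0.112 (0.0203 to 0.331) and Gm37906 of 0.0663 (0.00147 to 0.389), while Gm46212 (-2.36), the neurotensin receptor gene Ntsr1 (-2.28) and the cation channel gene Trpv4 (-2.23) made up the rest. Gm42892, Gm37613, Gm43421 and Gm37906 overlap abundant genes on their own strand (Palmd, Nav2, Zfp644 and Phf3). On the other strand, Gm46212 shares 1170 bases with the abundant gene Adgrg6 (mean 7.15 for Gm46212 and 1822 for Adgrg6). Gm15319 and Hapln1 overlap genes with few reads on the other strand (Gm26804 and Gm8546). These intervals and floors cover counting error only. Lpo, a lactoperoxidase gene chosen after its values were seen, had the smallest p of all genes and rose from 685 ± 82.3 to 1848 ± 87.6 (1.44; adjusted p = 1.3e-05), in all 6 fits without 1 library. Leaving out 1 library ended 1 or more calls among these genes in each of the 6 cases; the highest adjusted p was 0.0653 for Klri1 (without shMina53 2), 0.103 for Cc2d2b (without shMina53 3), 0.101 for Slc39a4 and 0.166 for Gm43421, the last pair not called in any of the 6 fits. Gm20482, Gm42892, Hapln1, Gm37613, Gm46212, Gm37906, Ntsr1 and Trpv4 were also lost in 1 or more fits, with adjusted p up to 0.181 (Gm37906, without shControl 2), and the fall of Trpv4 was -1.48 without shMina53 1. Aldh1a1, Btla and Gm15319 stayed called in all 6, with adjusted p up to 0.0394.

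Genes of the oligodendrocyte lineage were lower in shMina53. Sox10 (ENSMUSG00000033006; chromosome 15, 79154908 to 79165240, minus strand), the transcription factor of that lineage, fell from 507 ± 10.5 to 219 ± 11.4 scaled counts (log2 fold change -1.21, SE 0.126; adjusted p = 7.5e-05). Pdgfra, the growth factor receptor of oligodendrocyte precursors, fell from 774 ± 68.3 to 447 ± 28.3, Gpr17, a receptor gene of differentiating precursors, from 3152 ± 688 to 1512 ± 324, and Cldn11, a claudin of the myelin sheath, from 164 ± 28.5 to 76.4 ± 23.4. All 4 held in each of the 6 fits that left out 1 library. Of 19 members tested, 8 were called lower, 2 higher and 9 not called, and adjusted over the list alone the count was likewise 8 lower and 2 higher. Without 1 library 4 to 9 were called lower. The list median was -0.38 (adjusted p = 0.00102 by camera, adjusted p = 0.321 with an estimated correlation). The higher members were Ptprz1, a receptor phosphatase gene that radial glia also express (59358 ± 7683 to 84651 ± 3463), and Mobp, a myelin gene with few reads (log2 fold change 2.52). Both lost their call without shControl 2, shMina53 2 or shMina53 3 (adjusted p up to 0.0823 and 0.15). Olig1 (0.14), Olig2 (0.02) and Cnp (0.07) were not called. Gpr17 shares 6640 bases with Lims2 on the other strand, which was lower too (-1.73). Without shMina53 2 the list's median was -0.24.

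**Figure D2:**
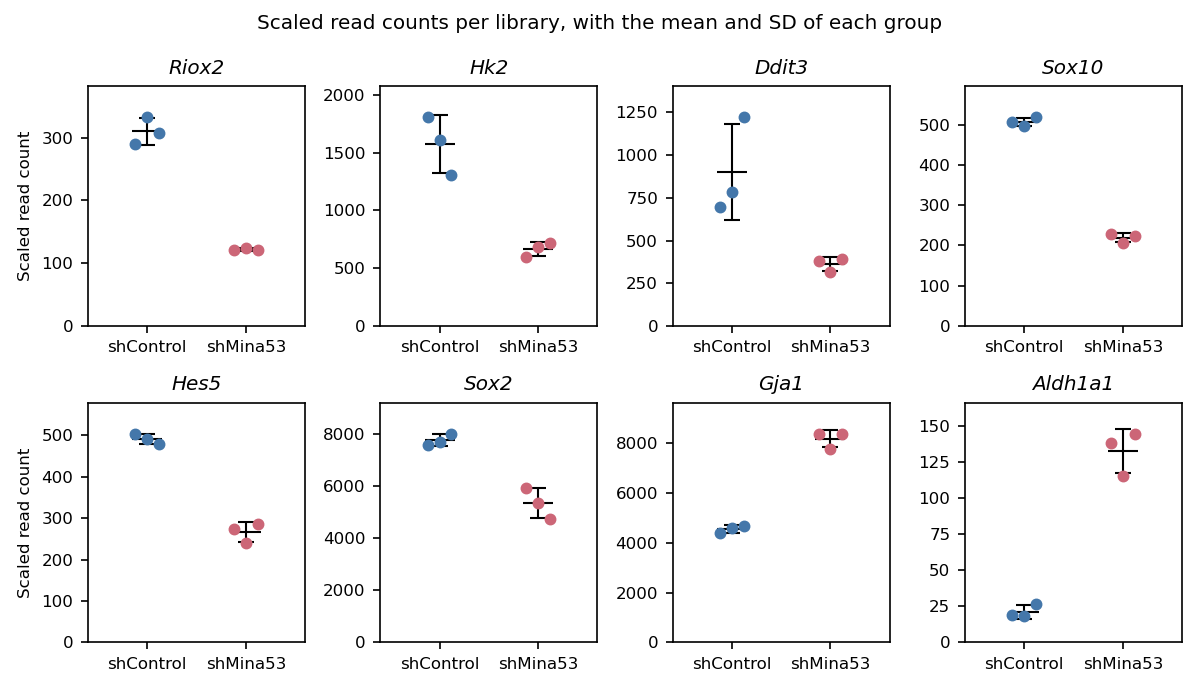
Scaled counts (vertical axis, from 0) of Riox2, Hk2, Ddit3, Sox10, Hes5, Sox2, Gja1 and Aldh1a1 in each library, 1 panel per gene and 1 point per library, with bars for the mean ± SD of n = 3. In shMina53 Gja1 and Aldh1a1 lie above all control libraries, at means of 8182 and 133, and the other 6 genes below them.

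Astrocyte genes moved the other way. Gja1 (ENSMUSG00000050953; chromosome 10, 56377330 to 56402513, plus strand), the gap junction protein connexin 43, rose from 4561 ± 148 to 8182 ± 342 scaled counts (log2 fold change 0.84, SE 0.101; adjusted p = 0.000208), and the water channel gene Aqp4 from 457 ± 50.8 to 749.6 ± 83.0. Gjb6, a further connexin gene, rose from 53.2 ± 13.3 to 110.3 ± 16.5, but was not called without shControl 2, shMina53 2 or shMina53 3 (adjusted p up to 0.0728). Gfap had 3196 ± 29.5 and 4056 ± 567 scaled counts (0.33; adjusted p = 0.079) and was not called, though it was without shControl 3 (adjusted p = 0.00931); without shMina53 3 its fold change was 0.22 (adjusted p = 0.313). Of 20 members 3 were called higher, 0 lower and 17 not called, and 5 were higher adjusted over the list alone. This count depends on the libraries and on length: 9 were called higher without shControl 3, 2 or 3 without any other library, and 8 with the length trend removed. Without shControl 1, 1 member was called lower. The members' median was 0.19 (camera adjusted p = 0.00136, adjusted p = 0.321 with an estimated correlation). At an unadjusted limma p under 0.05, 0 members were lower, and edgeR called 3 members in all.

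Neuronal genes were lower. The microtubule genes Stmn3 and Mapt fell from 1074 ± 218 to 587 ± 32.1 and from 2960.2 ± 289 to 1877 ± 108 scaled counts, with log2 fold changes of -0.85 and -0.65. Gap43, of growing axons, fell from 3642 ± 606 to 2341 ± 89.5 (-0.63), and Gad1, which makes the transmitter GABA, from 1580.3 ± 79.8 to 1094 ± 144 (-0.54). Gap43 was not called without shMina53 3 (adjusted p = 0.0508) and Gad1 not without shMina53 1 or shMina53 2 (up to 0.068). Of 33 members 6 were called lower, 1 higher and 26 not called, and adjusted over the list alone 10 were lower and 1 higher. Without shControl 3, 10 were called lower, and without any other library 3 to 5. The median fold change was -0.23 (camera adjusted p = 0.000892, adjusted p = 0.321 with an estimated correlation). The member called higher was the dendritic microtubule gene Map2 (0.37), which lost its call without shControl 2 or any 1 shMina53 library (adjusted p up to 0.204). The list of neural stem and progenitor identity, by contrast, went both ways: 5 of 29 members were called higher, 4 lower and 20 not called, with 8 higher and 4 lower adjusted over the list alone and, when 1 library was left out, 0 to 7 higher and 1 to 5 lower (camera adjusted p = 0.779; median -0.03, mean 0.02, test direction up). Hes5, a Notch target that holds progenitors undifferentiated, fell from 491 ± 12.7 to 266 ± 23.1 (-0.88; adjusted p = 0.000598). Sox2, the pluripotency and neural progenitor factor, fell from 7743 ± 222 to 5334 ± 587 (-0.54) and Hes1 from 721 ± 72.6 to 481 ± 63.1, while the orphan nuclear receptor gene Nr2e1 rose from 463 ± 71.7 to 722 ± 88.5. Sox2 and Nr2e1 were not called without shMina53 3 (adjusted p = 0.0606 and 0.0835), nor was Hes1 without shControl 2 or shMina53 3 (up to 0.0831). Of the 28 Notch pathway members 3 were called higher and 8 lower, with 17 not called and 6 higher and 10 lower adjusted over the list alone. Without 1 library 1 to 4 were called higher and 2 to 8 lower. The list did not pass (camera adjusted p = 0.779; median 0.09, mean -0.08, test direction down). Its members included the inhibitory ligand gene Dll3, down from 1347 ± 87.4 to 662 ± 184, the Notch glycosyltransferase gene Lfng, up from 2967 ± 175 to 4923 ± 371, and the Notch antagonist gene Numbl, down from 656 ± 113 to 418 ± 8.86 but not called without shControl 2 or shMina53 3 (adjusted p up to 0.071).

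Ribosomal protein genes were lower in shMina53. Rpl8 and Rpl5 of the large subunit had 10351 ± 1889 and 10564 ± 2362 scaled counts in shControl and 6382 ± 943 and 6629 ± 37.6 in shMina53, and Rps13 of the small subunit fell from 3911 ± 808 to 2215 ± 396. Of 46 large subunit genes 27 were called lower, 0 higher and 19 not called, with 41 lower adjusted over the list alone. The number called lower ran from 1 without shMina53 3 to 40 without shControl 1. Over these genes the median was -0.56 (camera adjusted p = 6.4e-22, adjusted p = 0.321 with an estimated correlation). Of 32 small subunit genes 18 were lower, 0 higher and 14 not called, with 27 lower adjusted over the list alone, and from 2 (without shMina53 3) to 27 (without shControl 1) called lower when 1 library was left out. The median was -0.52 (camera adjusted p = 1.1e-15, adjusted p = 0.321 with an estimated correlation), and -0.34 without shControl 3. At an unadjusted limma p under 0.05, 0 members of either list were higher, and edgeR called 27 and 17 members. Rpl13a, Rpl8, Rpl5 and Rpl23, and Rps16, Rps9 and Rps3a1, were not called without shMina53 3 (adjusted p = 0.058 to 0.0739). Rps13 was called in all 6 fits. The median deviation of the large subunit genes from their mean over all libraries was 0.63 in shControl 3, 0.21 in shControl 2 and -0.00448 in shControl 1, against -0.19, -0.24 and -0.38 in shMina53 1, 2 and 3. The share of reads on ribosomal protein genes was 3.29% ± 0.698 in shControl, with 4.06% in shControl 3, and 2.26% ± 0.107 in shMina53 (exact permutation p = 0.1). Genes of ribosome biogenesis were lower by less: of 32, 6 were called lower, 0 higher and 26 not called, with 8 lower adjusted over the list alone and 0 to 9 called lower when 1 library was left out. Without shControl 1, 2 were called higher. The list median was -0.20 (camera adjusted p = 0.000892, adjusted p = 0.321 with an estimated correlation), and -0.13 without shControl 3. The nucleolar protein gene Nop16 (-0.52), the polymerase subunit gene Polr1c (-0.54), Nob1 (-0.52) and Nhp2 (-0.66) were the members with the smallest p, and each lost its call without shControl 2, shMina53 2 or shMina53 3 (adjusted p up to 0.154), Nop16 and Polr1c also without shMina53 1 and Nhp2 without shControl 3.

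Glycolysis genes were lower as a group. Hk2 (ENSMUSG00000000628; chromosome 6, 82725025 to 82774454, minus strand), which encodes the hexokinase that traps glucose in the cell, fell from 1572 ± 252 to 668 ± 61.5 scaled counts (log2 fold change -1.23, SE 0.129; adjusted p = 7.5e-05). The neuronal-type glucose transporter gene Slc2a3 fell from 3132 ± 62.8 to 1578 ± 71.5, the lactate exporter gene Slc16a3 from 737 ± 38.1 to 404 ± 66.9, and Eno2, an enolase, from 819 ± 88.2 to 482 ± 34.7. All 4 genes stayed called whichever library was left out. Of 22 members 12 were called lower, 0 higher and 10 not called, with 15 lower adjusted over the list alone and 7 to 14 called lower when 1 library was left out. Without shMina53 3, 1 was called higher. The members' median was -0.46 (camera adjusted p = 1.7e-10, adjusted p = 0.321 with an estimated correlation). Cholesterol synthesis genes were lower too, with 9 of 22 called lower, 0 higher and 13 not called, and 15 lower adjusted over the list alone. Without 1 library the number was 2 to 12. The median fold change was -0.37 (camera adjusted p = 2.5e-09, adjusted p = 0.321 with an estimated correlation). Idi1, an isomerase of the isoprenoid chain, went from 1562 ± 264 to 854 ± 8.23, and Fdft1, squalene synthase, from 2999 ± 555 to 1834 ± 114. Fdft1 shares 774 bases with Ctsb on the other strand. Mvd (-0.67) and Acat2 (-0.58) fell as well but lost their call without shMina53 3 (adjusted p = 0.0606 and 0.0705), Acat2 also without shMina53 2.

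Mitochondrially encoded transcripts were higher, while the lower median of the nuclear genes of respiration rested mainly on shControl 3. Of 38 nuclear oxidative phosphorylation genes 5 were called lower, 0 higher and 33 not called, with 7 lower adjusted over the list alone and 0 to 15 called lower when 1 library was left out. Without shControl 3, 1 was called higher. Over these genes the median was -0.22 (camera adjusted p = 1.5e-06, adjusted p = 0.481 with an estimated correlation). It was -0.36 without shControl 1, -0.08 without shControl 3 and -0.12 with the length trend removed, past the threshold at the preset correlation in each. The list's median deviation was -0.128, 0.0764 and 0.45 in shControl 1, 2 and 3. In shMina53 1, 2 and 3 it was -0.0112, -0.0971 and -0.177. The groups therefore overlapped, with shControl 1 under shMina53 1 and 2. Ndufa2 of complex I fell from 965 ± 186 to 581 ± 97.2 scaled counts and cytochrome c, Cycs, from 2238 ± 366 to 1491 ± 193, both not called without shMina53 3 (adjusted p = 0.0733 and 0.105). Sdhd (-0.46) and Ndufb3 (-0.56) were not called without shControl 2, shMina53 2 or shMina53 3 (up to 0.214). Of 13 mitochondrially encoded transcripts 6 were called higher, 0 lower and 7 not called, with 9 higher adjusted over the list alone and 2 to 6 called higher when 1 library was left out. The median was 0.56 (camera adjusted p = 2.8e-06, adjusted p = 0.321 with an estimated correlation). mt-Nd5 rose from 34820.2 ± 2105 to 63723 ± 10438 and mt-Nd2 from 35125 ± 5511 to 64107 ± 12628, in all 6 fits. mt-Nd4 (0.60) and mt-Nd1 (0.56) were lost without shControl 2 or shMina53 3 (up to 0.122), mt-Nd1 also without shMina53 2. With quantile normalization the rise of mt-Nd1 was 0.157 (adjusted p = 0.421), and it was not called with the GC trend removed (0.41; adjusted p = 0.0705). The mitochondrial share of all reads was 3.04% ± 0.319 in shControl and 4.33% ± 0.527 in shMina53 (exact permutation p = 0.1), a share also read as a sign of RNA or cell quality. At an unadjusted limma p under 0.05, 0 glycolysis, 0 cholesterol and 0 oxidative phosphorylation genes were higher and 0 mitochondrial transcripts lower, and edgeR called 12, 8, 4 and 6 members of the 4 lists.

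Most of the called genes of the integrated stress and unfolded protein response were lower. Ddit3 (ENSMUSG00000025408; chromosome 10, 127290774 to 127296288, plus strand), the stress factor CHOP, fell from 901 ± 281 to 364 ± 40.7 scaled counts (log2 fold change -1.27, SE 0.178; adjusted p = 0.000936). Trib3, a pseudokinase induced by CHOP, fell from 277 ± 29.3 to 119 ± 17.0 and Chac1, a glutathione-degrading enzyme gene of the same arm, from 589 ± 94.5 to 299 ± 5.47, whereas the cystine transporter gene Slc7a11 rose from 1379.7 ± 109 to 2456 ± 170.0. All 4 held in each of the 6 fits. Of 28 members 11 were called lower, 1 higher and 16 not called, with 14 lower and 1 higher adjusted over the list alone. Without 1 library 4 to 14 were called lower. The list median was -0.34 (camera adjusted p = 9.8e-06, adjusted p = 0.321 with an estimated correlation), and -0.21 without shControl 3. Atf4, the factor at the centre of the response and chosen after its values were seen, fell from 4265 ± 815 to 2690.3 ± 290.2 and was not called without shMina53 3 (adjusted p = 0.073). Ddit3 shares 68 bases with Mars on the other strand, whose mean was higher than its own. Among immediate early genes Klf4 fell from 333 ± 23.4 to 164 ± 17.6, Ier3 from 768 ± 75.7 to 477 ± 49.2 and Jun, a subunit of AP-1, from 5586 ± 236 to 3797 ± 177, while the ERK phosphatase gene Dusp6 rose from 4079 ± 317 to 5638 ± 109 but lost its call without shControl 2, shMina53 2 or shMina53 3 (adjusted p up to 0.0892). Of these 21 genes 5 were called lower, 2 higher and 14 not called, with 6 lower and 2 higher adjusted over the list alone, and 3 to 6 called lower when 1 library was left out. The members' median was -0.22 (camera adjusted p = 0.00188, adjusted p = 0.39 with an estimated correlation), and -0.15 without shControl 3. With length and GC trends both removed the list did not pass (-0.14; adjusted p = 0.0594).

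Genes of mitosis were slightly lower and those of DNA replication were not called. Of 36 mitosis genes 5 were called lower, 0 higher and 31 not called, with 8 lower adjusted over the list alone and 0 to 6 called lower when 1 library was left out. Without shControl 1, 1 was called higher. The median fold change was -0.13 (camera adjusted p = 0.000487, adjusted p = 0.481 with an estimated correlation), and the list did not pass without shControl 1 (-0.08; adjusted p = 0.0606). It was -0.21 without shControl 3 and -0.21 without shMina53 1. The ubiquitin enzyme gene Ube2c fell from 1450.1 ± 171 to 1052 ± 93.9 scaled counts and the kinase gene Aurka from 504 ± 35.9 to 366 ± 39.9. These, Cdc25c (-0.62) and Ccna2 (-0.38) were lost without shControl 2, shMina53 2 or shMina53 3 (adjusted p up to 0.186), Ccna2 also without shControl 1 or shMina53 1. Of 41 replication genes limma called 0, and 0 adjusted over the list alone, with 2 higher and 2 lower at an unadjusted p under 0.05 and 0 called by edgeR. Over these genes the median was 0.05 (camera adjusted p = 0.779). Orc6 had 516 ± 69.6 and 396 ± 15.4 scaled counts, Ccne2 262 ± 31.8 and 335 ± 8.43, Pole 387 ± 137 and 508 ± 14.5, and Pcna 2478 ± 398 and 2053 ± 88.0 in shControl and shMina53. Without shControl 1, Orc6 was called lower and Pole higher (adjusted p = 0.0379 and 0.00256), while without shControl 3 the fold change of Pole fell from 0.45 to 0.21. p53 targets and cell cycle inhibitors went both ways, with 4 of 30 called higher, 5 lower and 21 not called, and 9 higher and 6 lower adjusted over the list alone. When 1 library was left out, 1 to 6 were called higher and 3 to 6 lower (camera adjusted p = 0.809; median 0.03, mean -0.05, test direction down). Cdkn1c, the inhibitor p57, fell from 98.1 ± 44.0 to 27.0 ± 5.98 (-1.76; adjusted p = 0.00191), the mTORC1 inhibitor gene Ddit4 from 5847 ± 141 to 3459.8 ± 207 and the cell death gene Bbc3 (PUMA) from 931 ± 86.1 to 561 ± 59.5. The p53-induced gene Trp53inp1 rose from 4083 ± 262 to 7175 ± 230.1, and these 4 stayed called in each fit that left out 1 library. Of 26 apoptosis genes 3 were called lower, 2 higher and 21 not called, with 4 higher and 5 lower adjusted over the list alone and 1 to 5 lower and 0 to 2 higher when 1 library was left out (camera adjusted p = 0.0849). The list passed without shControl 1 (adjusted p = 0.0486).

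Of the 17 arginine methyltransferase and related JmjC enzyme genes 1 was called. Jmjd6 (ENSMUSG00000056962; chromosome 11, 116837432 to 116843449, minus strand), which encodes another JmjC oxygenase, fell from 2222 ± 143 to 1159 ± 99.2 scaled counts (log2 fold change -0.94, SE 0.110; adjusted p = 0.000164). The other 16 were not called, and adjusted over the list alone 0 were higher and 1 lower. The median was -0.05 and ran from -0.125 to 0.0013 when 1 library was left out. The list did not pass camera (adjusted p = 0.145), though it passed fry (adjusted p = 0.0151). Prmt1, the main type I methyltransferase, had 3302 ± 439 and 2683 ± 124 scaled counts, Carm1 911 ± 245 and 1117 ± 58.1, and Smn1, which binds methylated arginine, 387 ± 37.0 and 320.1 ± 17.5. Carm1 was called higher without shControl 1 (adjusted p = 0.0483), while without shControl 3 its fold change was 0.09. Jmjd6 shares 172 bases with Mettl23 on the other strand. Polycomb genes were slightly lower, with 4 of 23 called lower, 0 higher and 19 not called, and again 4 lower and 0 higher adjusted over the list alone, or 2 to 4 called lower when 1 library was left out. The list median was -0.10 (camera adjusted p = 0.023, adjusted p = 0.321 with an estimated correlation), but the list did not pass without shMina53 2 (-0.06; adjusted p = 0.0698). It was -0.06 too without shControl 3, and the list did not pass with quantile normalization (adjusted p = 0.0598), with edgeR's log values (0.0646) or among genes with a mean of at least 10 (0.0642) or 50 (0.114). Cbx8, a subunit that reads histone methylation, fell from 262 ± 38.1 to 142 ± 12.3 scaled counts. Pcgf2 (-0.67) and Jarid2 (-0.44) were lost without shControl 2, shMina53 2 or shMina53 3 (adjusted p up to 0.14), Pcgf2 also without shMina53 1. Of 5 Hox genes with enough reads 1 was called lower, Hoxa5 (29.3 ± 6.79 to 11.5 ± 3.63 scaled counts), with 0 higher, 4 not called and 3 lower adjusted over the list alone. The members' median was -1.09 (camera adjusted p = 0.0113, adjusted p = 0.321 with an estimated correlation), and ran from -1.24 to -0.563 over the alternatives. Hoxa4 had 17.7 ± 4.71 and 7.93 ± 1.72, Hoxa3 13.5 ± 1.97 and 5.97 ± 1.84 and Hoxa2 5.99 ± 4.25 and 1.79 ± 1.61 scaled counts. Hoxa3 overlaps Hoxa4 and Hoxa5 on the same strand, the list did not pass without shControl 3 (adjusted p = 0.0561), and Hoxa5 was lost without shControl 2 or any 1 shMina53 library (up to 0.173).

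Hedgehog pathway genes were higher. Hhip, a Hedgehog-binding target gene, rose by a log2 fold change of 0.84, in all 6 fits. Ccnd1 (cyclin D1) rose from 17497 ± 1514 to 25326 ± 1199.6 scaled counts, though it was not called without shMina53 2 (adjusted p = 0.0612). Gli3, mainly a repressor of the pathway, rose from 117 ± 27.2 to 192 ± 14.6 but was lost without shControl 2 or any 1 shMina53 library (up to 0.0977). Boc had 190.4 ± 43.1 and 253 ± 14.6 and was called only without shControl 1 (adjusted p = 0.0447), with a fold change from 0.43 overall to 0.23 without shControl 3. Of 13 members 3 were called higher, 0 lower and 10 not called, the same as adjusted over the list alone. When 1 library was left out 1 to 5 were called higher, and 1 was called lower without shControl 1. The median fold change was 0.28 (camera adjusted p = 0.00594, adjusted p = 0.35 with an estimated correlation), and 0.16 without shControl 3. At an unadjusted limma p under 0.05, 1 Hedgehog gene was lower and 0 Polycomb, 0 Hox, 0 mitosis and 1 ribosome biogenesis gene higher, and edgeR called 3, 4, 1, 4 and 4 members. The remaining lists did not pass. Of 18 Wnt targets 3 were called higher and 1 lower (camera adjusted p = 0.591; median 0.07, mean -0.06, test direction up), of 19 BMP and TGF-beta response genes 2 higher and 1 lower (0.314), of 31 interferon response genes 2 higher and 1 lower (0.326), and of 31 extracellular matrix genes 4 higher and 4 lower (0.176; 0.0353 without shControl 1). Adjusted over the list alone these counts were 3 and 1, 2 and 1, 2 and 1, and 7 and 5. When 1 library was left out, 0 to 3 Wnt targets were called higher and 1 or 2 lower, 0 to 3 BMP and TGF-beta response genes higher and 1 or 2 lower, 0 to 3 interferon response genes higher and 0 or 1 lower. For extracellular matrix genes 2 to 8 were higher and 0 to 4 lower.

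The lists of markers of other cell types did not pass camera. Of 10 ependymal genes 1 was called higher, the cilium factor gene Foxj1 (228 ± 16.8 to 409 ± 62.2 scaled counts), and 1 lower, Tm4sf1 (log2 fold change -0.87, not called without shControl 2 or any 1 shMina53 library, adjusted p up to 0.131), both chosen after their values were seen (camera adjusted p = 0.278). The ependymal median was 0.27, but ran from 0.164 without shMina53 1 to 0.606 without shMina53 3, and this list passed fry (adjusted p = 0.0452). limma called 0 of 7 microglia and macrophage genes (0.779), 0 of 8 endothelial genes (0.906) and 0 of 11 fibroblast and mural cell genes (0.296; median 0.64, 0.406 without shMina53 2 and 0.0363 among genes with a mean of at least 10); at an unadjusted p under 0.05 they held 0, 0 and 2 genes higher and 0, 1 and 1 lower, and edgeR called 0, 0 and 0. Adjusted over the list alone, 2 ependymal genes were higher and 1 lower, and of the other 3 lists 0, 0 and 0 higher and 0, 0 and 0 lower. An erythroid list was not tested, since 2 of its 11 genes had enough reads.

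**Figure D3:**
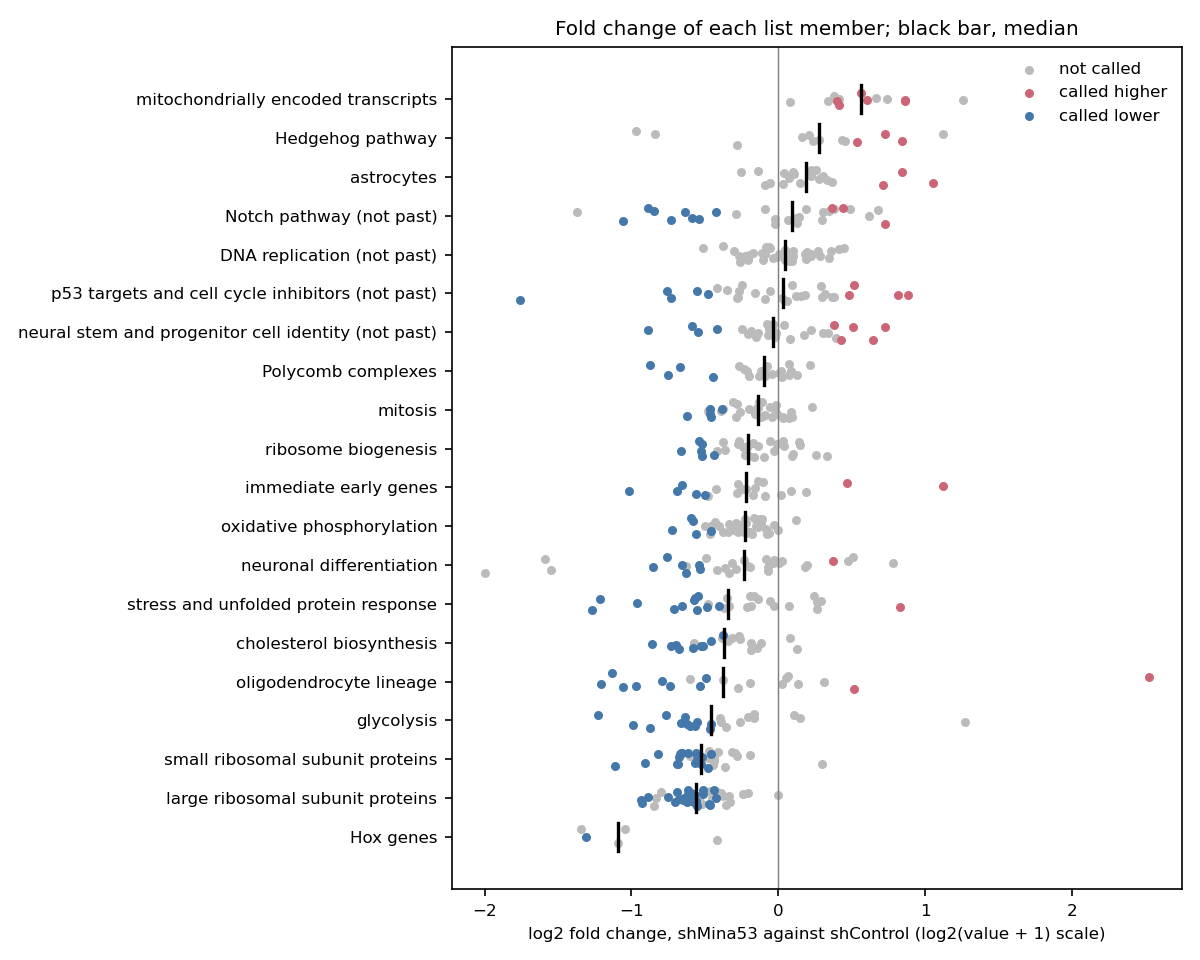
Log2 fold change of shMina53 over shControl (horizontal axis) of the tested members of 20 lists, 1 point per gene, coloured where called, with a black bar at the list's median and a mark at lists not past the camera test. The bars lie at -0.56 for the large ribosomal subunit, -0.46 for glycolysis and 0.56 for mitochondrially encoded transcripts.

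Over 11377 protein-coding genes, the fold change rose with transcript length (Spearman 0.432 across genes, which are not independent), from a median of -0.29 in the decile with the shortest transcripts to 0.22 in the decile with the longest. Called genes that were higher had a median transcript of 4644 bases and those lower of 2338. Within libraries the correlation of a gene's deviation from its mean with length was 0.272, -0.22 and -0.661 in shControl 1, 2 and 3 and 0.2, 0.39 and 0.412 in shMina53 1, 2 and 3 (exact permutation p = 0.2 between groups), so shControl 3 stood furthest from the others. Without shControl 3 the fold change still rose with length (Spearman 0.227, bootstrap 95% interval 0.21 to 0.245). The bootstrap resampled genes, so this interval does not cover the spread between libraries. The ribosomal protein genes had short transcripts, with a median of 1054 bases in the large subunit. With the length trend of each library removed, all 16 lists passed, and the medians were -0.46 for the large subunit, -0.44 for glycolysis, -0.46 for the oligodendrocyte lineage and 0.17 for astrocytes; without shControl 3 all but Hox genes passed.

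**Figure D4:**
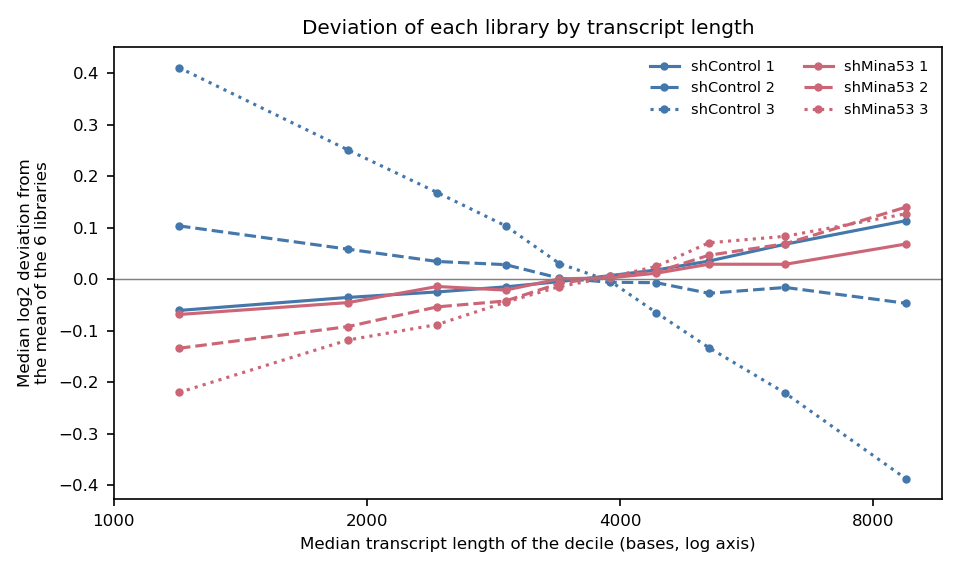
Median log2 deviation of each library from the gene's mean over all 6 libraries (vertical axis) by decile of transcript length (horizontal axis, bases, log scale), 1 line per library. shControl 3 runs from 0.41 in the shortest to -0.39 in the longest transcripts, and the 3 shMina53 libraries rise.

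Of the 30 lists tested, 16 passed the camera test, 13 lower and 3 higher in shMina53. With an estimated correlation none passed (0 lists; lowest adjusted p = 0.321), and 2 had an unadjusted p under 0.05; fry, which asks whether a list's own genes move one way, passed 11 lists, among them the arginine methyltransferase and ependymal lists that did not pass camera. Of the 16 lists, 7 did not pass fry: both ribosomal subunits, the stress response, oxidative phosphorylation (adjusted p = 0.334), mitosis (0.25), immediate early genes (0.0741) and Hedgehog (0.0741). In the authors' deposited table, the number of genes with a p-value under 0.05 was 4188, of which 1918 were higher and 2270 lower. Adjusting those p-values gave 1628 genes, of which 1514 were also called by limma. The p-value of Riox2 in the authors' deposited table was 6.44e-14.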

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

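The alternatives chosen after the data were seen were the fits on recovered reads (edgeR, DESeq2), the removal of length and GC trends, a pseudocount of 10 and the filters at means of 10 and 50; the rest were fixed beforehand. Those fixed for a table of counts (edgeR with TMM or RLE, no filter, DESeq2) were not run as written, since the table held scaled counts, and were run on recovered reads instead. Riox2 stayed called under every alternative, with a log2 fold change from -1.40 to -1.27 and, when 1 library was left out, from -1.38 to -1.28; its adjusted p went up to 0.0395. No named gene changed direction. Besides limma without trend and robust and the fits without 1 library, 14 named genes lost their call with the replicate block, 9 with the deposited p-values, 9 with a pseudocount of 0.1 and up to 3 elsewhere; mt-Nd1 was lost with quantile normalization (0.157; adjusted p = 0.421). With the replicate number as a block 1178 genes were called, 624 of them lower, and 1137 were also called without it. Deviations of libraries with the same number correlated at -0.145, 0.107 and 0.0198. Those of libraries from both groups with different numbers ran from -0.15 to 0.0802. No signal shared by number was seen, but this cannot show whether samples were prepared in pairs, and the labels do not say what a number marks. Leaving out 1 library gave 497 to 2794 genes, 224 to 1383 higher and 273 to 1411 lower, with 79 to 324 doubled and 65 to 170 halved, and 15 to 17 lists; each of these fits has fewer samples. limma without trend and robust called 32 genes (18 higher, 14 lower), all 18 at least doubled and all 14 at least halved. Its 16 lists say nothing on this setting, since camera here did not use those steps. The other totals lay between 1566 and 2633. Doubled genes numbered 112 with the deposited p-values, 87 (and 72 halved) with a pseudocount of 10, which shrinks fold changes of low counts, and 69 at a mean of at least 50, which tests fewer genes. Lower genes numbered 1538 with edgeR and no filter and 1513 with length and GC trends removed; the cause was not tested. Of the lists, 0 passed with an estimated correlation, and 2 had an unadjusted p under 0.05; fry passed 11. All other alternatives that tested lists passed 14 to 16.

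Medians that changed sign belonged to lists that did not pass. Endothelial genes came to 0.145 with no filter, 0.119 with edgeR and no filter, 0.0124 with the GC trend removed and 0.0139 with a pseudocount of 10, and ranged from -0.117 to 0.0971 when 1 library was left out. Microglial genes came to -0.0478 with edgeR and no filter and -0.0111 with a pseudocount of 10 (range -0.0296 to 0.515). Wnt targets came to -0.0174 with quantile normalization (-0.0408 to 0.168), and p53 targets to -0.018 with the length trend removed and -0.0152 with length and GC removed (-0.0512 to 0.0544). Neural stem cell genes came to 0.00614 with length and GC removed and 0.0484 with GC alone (-0.075 to 0.0397), extracellular matrix genes to -0.0111 with length and GC removed, and replication genes to -0.00377 with GC removed (-0.0464 to 0.121). Arginine methyltransferase genes ranged from -0.125 to 0.0013 when 1 library was left out. The cause was not tested. In data simulated at this depth with 3 libraries per group, 59% of genes changed 1.5-fold and 96% of genes changed 2-fold were called, and 14 of 14852 unchanged genes. The changed genes were drawn only from those with a mean of at least 50 reads, so the 59% and 96% do not cover genes with fewer reads.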

Other observations

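The lists of cilium genes and of hypoxia-inducible factor targets, the tests of cilium genes without some members, the tests with the length trend removed, the comparison of length trends between libraries and the count of abundant oligodendrocyte genes were chosen after the results they bear on were seen.

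Genes of motile cilia were among those that rose in shMina53. The axonemal gene Cfap44 rose from 11.3 ± 4.88 to 58.8 ± 5.73 scaled counts (log2 fold change 2.34; adjusted p = 0.000539), Cfap54 from 46.3 ± 7.27 to 121 ± 15.1 and Cfap69 from 38.4 ± 5.67 to 92.4 ± 16.0, all called whichever library was left out. The dynein heavy chain gene Dnah9 rose from 4.71 ± 4.32 to 24.9 ± 5.58 but was not called without shMina53 3 (adjusted p = 0.0955). Of 61 cilium genes listed 56 were tested (4 of them on the ependymal list too), of which 9 were called higher, 0 lower and 47 not called, with a median of 0.39. Without 1 library 3 (without shMina53 3) to 10 were called higher. The list was drawn up because Cfap44 and Dnah9 stood out, so its own test restates that. Without both genes the other 54 had a median of 0.385, with 41 of them higher (camera p = 0.000244, 0.0138 with an estimated correlation). Without all called genes the other 47 had a median of 0.297, with 34 higher (camera p = 0.0242, but 0.0603 with an estimated correlation). These 47 were picked by the same fold changes, so their p-values are no test of a joint rise. Markers of ependymal cells, another cell type with motile cilia, are only partly separate from these genes, since 4 are on both lists. None of the 4 was called. Dnah11 (log2 fold change 1.65, few reads) and Rsph1 (0.89) had adjusted p = 0.151 and 0.194. Dnah5 (0.08) and Cfap126 (0.02) were close to unchanged (adjusted p = 0.95 and 0.983). The ependymal list's median was 0.27, with 7 of 10 members higher (camera adjusted p = 0.278, fry 0.0452), and its lowest median under any alternative was 0.081. Of its most abundant members Foxj1, the factor that turns on motile cilia, rose (228 ± 16.8 to 409 ± 62.2), Tm4sf1 fell (log2 fold change -0.87, from a mean of 146) and Cfap126 was not called (0.02, from a mean of 30.9). A joint rise of cilium genes is a hypothesis found on these data, and whether it comes from more cells of another type stays open.

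Most of the listed targets of the hypoxia-inducible factor were lower, with and beyond glycolysis. Ndrg1 fell from 328 ± 28.1 to 118 ± 13.4 scaled counts (-1.47; adjusted p = 7.5e-05), the collagen hydroxylase genes P4ha2 and P4ha1 by log2 fold changes of -0.74 and -0.61, and the histone demethylase gene Kdm3a from 3380.5 ± 382 to 2246 ± 178, each in all 6 fits without 1 library. Of 18 targets, none on another list (0 genes), 10 were called lower, 0 higher and 8 not called, and 6 (without shMina53 3) to 12 were called lower when 1 library was left out. The median was -0.45 (-0.46 with the length trend removed, -0.40 without shControl 3). camera gave p = 1.2e-11 (0.0436 with an estimated correlation). Vegfa had 13922 ± 1759 and 11147 ± 1570.0 scaled counts and was not called. Nor were Higd1a (-0.39), Plod2 (-0.29), Egln1 (-0.27), Bnip3l (-0.23), Egln3 (-0.14), Car12 (0.11) and Car9 (0.05). Lower activity of the factor may accompany the lower glycolysis genes; oxygen and medium were not compared here and stay open.

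Fold changes rose with transcript length (Spearman 0.432 across genes), and shControl 3 departed most from the other libraries. shControl 3 alone does not carry the trend, since without it the correlation was 0.227. Length trends also vary between libraries of 1 group, and the lowest correlation of a shMina53 library lay under the highest of a shControl library (difference -0.0713); with 3 libraries per group this cannot decide whether the trend is due to the knockdown. RNA integrity or library preparation per sample could produce such a trend. The mitochondrial share of reads, a sign of RNA or cell quality, was 2.97%, 2.77% and 3.39% in shControl 1, 2 and 3 and 3.90%, 4.19% and 4.92% in shMina53 1, 2 and 3. This sign differs between the groups, and the part due to the knockdown stays open.

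Ribosomal protein genes were lower, with 45 of 78 called and a median of -0.55; without shMina53 3, 1 large and 2 small subunit genes were called. The length trend does not account for it as a whole, since the median was -0.45 with that trend removed, nor does shControl 3 alone, as it was -0.38 without that library. Reads moving from parent genes to pseudogenes would raise the pseudogenes, but 131 ribosomal protein pseudogenes had a median of -0.42 (bootstrap interval -0.45 to -0.28). The bootstrap resampled pseudogenes, so its interval does not cover the spread between libraries. A lower output of ribosomal protein genes in knockdown cells is a candidate explanation, beside a loss of short transcripts that a length curve does not capture and a difference in RNA quality. The mitochondrial share differed between the groups too, and shMina53 3 had both the highest mitochondrial share (4.92%) and the lowest share of ribosomal protein reads (2.14%), though within shControl the library with the highest mitochondrial share, shControl 3 (3.39%), also had the highest ribosomal share (4.06%). RNA quality was not separated from the knockdown here; with an estimated correlation the adjusted p was 0.321.

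Oligodendrocyte lineage and neuronal genes were lower and astrocyte genes higher. With an estimated correlation none of these lists passed (adjusted p = 0.321 for each). At the preset correlation all 3 lists passed in their direction with the length trend removed (3 of 3 lists) and without shControl 3 (3 of 3 lists). Splits that mix shControl and shMina53 libraries also passed 4 to 11 lists by this test, so passing it excludes neither cause. The oligodendrocyte, neuronal and astrocyte medians were -0.46, -0.29 and 0.17 with the length trend removed. Without shControl 3 they were -0.42, -0.26 and 0.24. The medians thus kept their direction without the fitted length curve or that library. A lower share of oligodendrocyte lineage cells in the knockdown cultures should lower all their abundant transcripts. Of 16 abundant members 11 were lower, of which 8 were called; 7 were not called and 1, Ptprz1, was called higher. Sox10 fell by -1.21, whereas Olig1 (0.14), Olig2 (0.02) and Cnp (0.07) were not lower, which speaks against a lower share unless other cells of the culture supply these transcripts and that of Ptprz1. Since such cells may express them, a change in cell share and a change of expression within cells cannot be told apart here. The number of called rises taken to exclude a lower share was at first 1, and was raised to 3 after the value of 1 was seen.

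The 6 libraries can be split into groups of 3 in 10 ways. Each split other than the real one mixes shControl and shMina53 libraries. A difference between the real groups then adds to the spread within each mixed group and lowers its calls. These splits are therefore no clean measure of chance. The real split gave 1776 genes and the highest other split 0 by limma (316 to 1350 genes at an unadjusted p under 0.05, and 0 by edgeR), so 1 of the 10 splits gave as many genes; 10 splits are too few for a share under 0.05. For lists the real split gave 16 and the highest other 11, the lowest 4, so 1 of the 10 splits gave as many lists; here too 10 splits are too few for a share under 0.05.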
